A study of Drosophila melanogaster with 6 samples.

How the data were processed

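RNA was measured from eye-antennal imaginal discs of wandering third-instar larvae of Drosophila melanogaster in 2 genotypes with 3 biological replicates each, 6 samples in all. Per the labels, both genotypes were in the w1118 strain and larvae were grown at 25 °C; the design text describes each replicate as pooled disc pairs, with a number that reads as 300. Total RNA was isolated with Trizol and RNeasy columns, cRNA was made with a one-cycle kit, labelled with biotin, and 15 ug was hybridised to each one-colour Affymetrix Drosophila Genome 2.0 array, per the labels' protocols.

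The deposited values are log2 intensities, 1 value for each of 18952 probe sets on each array. The authors made them with GCRMA, per the submitters' processing notes, and its version is not given in the sources used here. GCRMA corrects the background by probe sequence, normalizes arrays and summarises the probes of a probe set. The log2 scale was taken from the values, which ran from a floor of 2.165 to 15.79. The arrays' quartiles were not identical, so full quantile normalization over all 6 arrays either was not the last step or was altered later. Nothing was normalized again for the values reported first. Array data have no read depth, and the number of arrays limits the precision. Values near the floor carry little information about level, so a fold against them is open below.

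The 183 Affymetrix control probe sets were set apart and used for quality measures. Of the other 18769 probe sets, GEO's platform annotation gave 1 gene for 13647, several genes for 402 and none for 4720. The gene identifiers of 13544 probe sets were found in the NCBI table of assembly Release 6, which was used for names alone; 103 kept their platform symbol. Probe sets with several genes or none were counted among probe sets and never named. A probe set was tested when its log2 value was at least 4 on at least 3 arrays, without regard to genotype, which left 7962 probe sets and 6447 genes. The labels call the samples biological replicates, so p-values measure the spread between pools of discs. Where a fit includes the replicate number, they measure the spread left after it. A gene was represented by its tested probe set with the highest mean over all arrays.

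Tumour and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. All adjusted p-values of single genes are from limma fits with these settings, described next, and all are two-sided. No covariate entered the fit chosen before the data were examined, called unpaired below. A fit with the replicate number as a block, called paired below, was the alternative fixed with it. The labels number the replicates 1 to 3 in both genotypes without saying what a number marks. Samples with the same number deviated together from their genotype means, with correlations across tested probe sets of 0.794, 0.467 and 0.723 for numbers 1, 2 and 3. All 3 lay over 0.1, a bound fixed in advance for treating the numbers as pairs. The correlations and the counts of both fits were first computed together, so the counts were known when the bound was applied. The pairing therefore comes from the data and not from the labels. Tumour replicate 2 correlated more with control replicate 3, at 0.668, than with its own number, and tumour replicate 1 correlated negatively with control replicates 2 and 3, at -0.524 and -0.776. The clearest part of the pairing was thus the split of replicate 1 from the rest. Replicates 2 and 3 alone were also fitted, without a block, a choice made after seeing the data.

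There were 36 gene lists, fixed together with the fit, with 492 distinct genes, of which 384 had a named probe set here and 317 were tested. The 28 lists with at least 4 tested genes were tested against all other genes with camera, with a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry; adjustment was over the lists. Members were also adjusted over the list alone. Genes named are Delta, lola, psq, w and ey; the 10 largest rises and 10 largest falls among genes past the threshold in the unpaired fit with no overlap between genotypes; and in each list up to 4 members past the threshold with the smallest adjusted p, or the 1 or 2 with the smallest p where none passed. Because the unpaired fit called 2 list members in all, Ilp8 and TpnC73F, the list part of the rule was applied to the paired fit, a choice made after seeing the data. Array quality measures were compared with exact permutation tests of means, for which the smallest two-sided p is 0.1 with 3 against 3.

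The fits were tested on simulated data made from the real probe-set means, replicate effects and paired-fit spread, with 200 of 7962 probe sets changed, in 5 runs. The unpaired fit recovered 0.8% of changes of 0.5 log2, 33.6% of 1, 83.2% of 2 and 96.4% of 4, with 0.2% false calls. The paired fit recovered 70.4%, 98.0%, 100% and 100% of them, with 6.2% false calls. The simulated replicate effects were shared by same-number samples, as the paired fit assumes. The simulation therefore cannot show that pairing by number holds, or that this share of false calls applies to the real data. For camera, 10 of 100 simulated lists of 13 randomly drawn genes were shifted by 0.4 log2, with independent noise added to the real replicate effects. The preset correlation called 10 of the 10 shifted lists and 0 of the 90 others, and the estimated correlation called 0 of the 10. In the real lists the estimated correlation ran from -0.034 for neuroblasts and neurons to 0.88 for retinal determination. The correlation within the simulated lists was not measured. Their genes were drawn at random and their added noise was independent, so their share of false calls does not carry over to the real lists.

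Alternatives were another filter, another variance moderation, 3 other scalings, a pseudocount of 16 on the linear scale, array weights, each array left out, the mean of a gene's probe sets, a 2-fold minimum and an adjusted p of 0.01. Gene families, taken as tested genes whose symbols share their leading letters, were screened after the data were seen with a one-sided Fisher's exact test and camera, adjusted over the families. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The genes w, N, Ser, Su(H), hth, wg, phm and others with no probe set named here were not analysed here.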

Results

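Gene expression was measured in eye-antennal discs, the larval epithelia that form the adult eye, antenna and head capsule. The tumour genotype carried ey-Gal4, which drives expression in the developing eye, with the GS(2)88A8 insertion and UAS-Dl, a transgene of the Notch ligand Delta. The control genotype carried GS(2)88A8 and UAS-Dl without the driver. In the published description of this combination, the GS line places lola and psq, a pair of genes for BTB-domain transcription factors, under Gal4 control. Each genotype had 3 arrays. The comparison asks which transcripts differ between discs with and without the driver. No genotype carried the driver alone, so effects of the driver itself cannot be told apart from those of the genes it drives.

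On each array between 7864 and 8004 probe sets reached a log2 value of 4. The replicate 1 arrays of both genotypes stood apart from the other 4 arrays. The first principal component of the tested probe sets, with 67.1% of the variance, separated them, and the second, with 23.3%, separated the genotypes. The 18S rRNA control averaged 13.1 log2 on the replicate 1 arrays against 8.27 on the others, and the actin 3'-minus-5' difference averaged 0.943 against 0.447. Between genotypes, the 18S rRNA control was 9.73 ± 3.7 in tumour and 10.04 ± 2.0 in control (SD, n = 3, exact permutation p = 0.8). The actin 3'-minus-5' difference was 0.609 ± 0.37 in tumour and 0.616 ± 0.23 in control (SD, n = 3, exact permutation p = 1). That of eIF4a was lower in tumour in each same-number pair, at 1.47 ± 0.21 against 1.66 ± 0.15 (SD, n = 3, exact permutation p = 0.2), and those of gapdh and Act5C had exact permutation p = 1 and 0.4. The median of the tested probe sets was 9.04 ± 0.18 against 9.02 ± 0.21 (SD, n = 3, exact permutation p = 0.7).

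**Figure D1:**
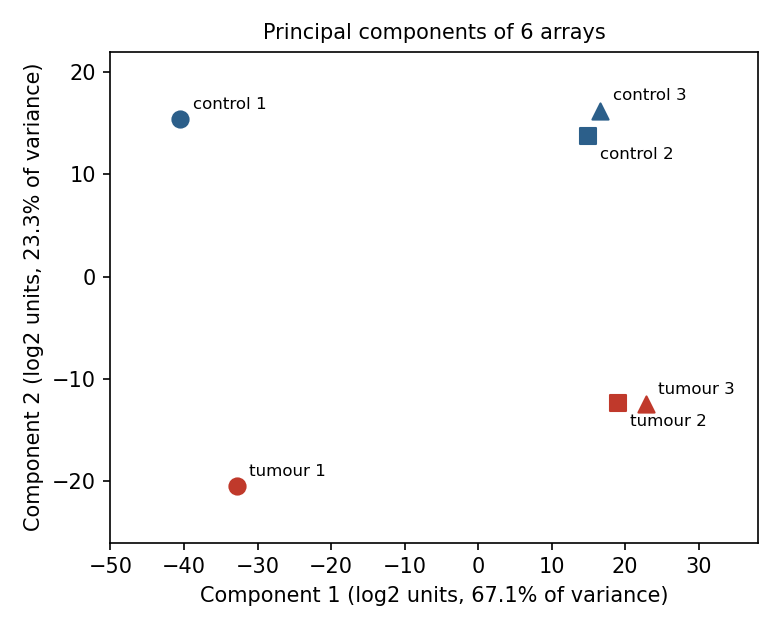
Principal components of the 6 arrays over the tested probe sets; the horizontal axis is component 1 (67.1% of variance) and the vertical axis component 2 (23.3%), both in log2 units, with tumour in red, control in blue and replicates 1, 2 and 3 as circles, squares and triangles. The replicate 1 arrays lie at -32.8 and -40.5 on component 1, and all tumour arrays lie below 0 on component 2.

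The 3 genes driven by the insertions did not differ between genotypes by limma on their representative probe sets. Delta had a log2 value of 11.19 ± 0.10 in tumour and 10.95 ± 0.49 in control (SD, n = 3), a difference of 0.24 (adjusted p = 0.98 unpaired, 0.33 paired), and its second probe set differed by 0.00. For psq the difference was 0.04 (adjusted p = 1 unpaired, 0.57 paired). For lola it was 0.46 (adjusted p = 0.46 unpaired, 0.10 paired), with all 3 tumour values above all 3 control values. The 13 tested lola probe sets ranged from -0.54 to 0.50, and 1 of them was called higher in the paired fit, by 0.29 (adjusted p = 0.049). All 3 genes had high values in the control discs, and whether the probe sets cover the driven transcripts is not known here, so these values do not check the labels. The driver's own gene ey, a master regulator of eye identity, was 10.32 ± 0.43 in tumour and 9.08 ± 0.60 in control (SD, n = 3), 2.36-fold higher in the paired fit (adjusted p = 0.0056) and not called in the unpaired fit (adjusted p = 0.32). The gene w was not analysed here.

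Across the genome, 33 of 6447 tested genes changed in the unpaired fit, 9 higher and 24 lower in tumour, among 41 of 7962 probe sets. In the paired fit 609 genes changed, 262 higher and 347 lower, and 118 of them by at least 2-fold, 25 higher and 93 lower. With replicates 2 and 3 alone 462 genes changed, 192 higher and 270 lower. All 33 genes of the unpaired fit were called in both of these fits. Of the 609 genes, 384 were called in the same direction with replicates 2 and 3 alone, and all 609 had the same sign in the 3 pairs. The paired fit favours genes whose pairs agree, and these fits share arrays, so none of these counts is independent support. Genotypes did not overlap for 1026 tested genes, 15.9% against the 10% that chance gives for 3 against 3 exchangeable arrays, a condition that the likeness of same-number arrays breaks. Leaving out 1 array moved the 33 genes to between 0 and 13: 13 without tumour replicate 1, 6 without control replicate 1, 1 without tumour replicate 3, and 0 without tumour replicate 2, control replicate 2 or control replicate 3, where limma's unadjusted p was under 0.05 for 366, 430 and 383 genes.

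Measured on each gene's brightest tested probe set, the largest measured rise among genes called in the unpaired fit was in Kots, from 2.18 ± 0.02 in control to 6.86 ± 0.50 in tumour (SD, n = 3, 4.68 log2, adjusted p = 0.0043). Its control values lay at the floor of the scale. Ilp8, a relaxin-like hormone released by damaged or overgrown discs that delays metamorphosis, rose from 3.01 ± 0.27 to 6.76 ± 0.91 (SD, n = 3, 3.74 log2, adjusted p = 0.040), again from near the floor, so that both rises are lower bounds and their order is open. Genes of cuticle proteins followed: Lcp65Ad rose by 2.25 and TwdlE by 1.41. The other rises were in CG15212 (1.39), RpS5b (1.35), a ribosomal protein paralogue known from the germline, CG6414 (1.03), the odorant-binding protein gene Obp44a (0.98) and CG5888 (0.87). On these brightest probe sets the unpaired fit called 9 rising genes in all, and their adjusted p-values lay between 0.0043 and 0.046. In the paired fit all 9 passed, with adjusted p-values from 0.0032 to 0.0093. Outside this ranking, the unpaired fit also called rises on probe sets that were not the brightest of their gene. They were in RFeSP (5.03 from near the floor, adjusted p = 0.018) and gkt (2.21, adjusted p = 0.022).

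Falls were likewise ranked among genes called in the unpaired fit, on each gene's brightest tested probe set. GV1 was not ranked, since the probe set called for it (-1.91, adjusted p = 0.004) was not its brightest. The largest measured fall was in CG7203, from 11.34 ± 0.40 in control to 7.44 ± 0.89 in tumour (SD, n = 3, -3.90 log2, adjusted p = 0.037). The pigmentation gene t, which encodes the hydrolase Tan, fell from 7.53 ± 0.40 to 3.76 ± 0.55 (SD, n = 3, -3.76 log2, adjusted p = 0.022), reaching values near the floor, so that its fall is a lower bound and its order against CG7203 is open. CG11854 fell by 2.76 to values near the floor, and the cuticle protein gene Cpr11B fell by 2.42. The next falls among genes called in the unpaired fit were in Jhbp14 (-2.13), CG13043 (-1.80), CG11131 (-1.63), the adenylate kinase gene Adk3 (-1.59), CG14109 (-1.54) and the yellow-family gene yellow-e (-1.50). By the rule of choice, each of these 10 genes was lower on all 3 tumour arrays than on any control array. Each was called in the paired fit, with adjusted p-values from 0.0015 to 0.012. Leaving out tumour replicate 2, control replicate 2 or control replicate 3 ended the unpaired calls of all 19 genes named as largest rises and falls. Leaving out tumour replicate 3 ended 18 of these calls, control replicate 1 ended 17 and tumour replicate 1 ended 10. No direction could change, since the genes were chosen for values that do not overlap between genotypes.

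**Figure D2:**
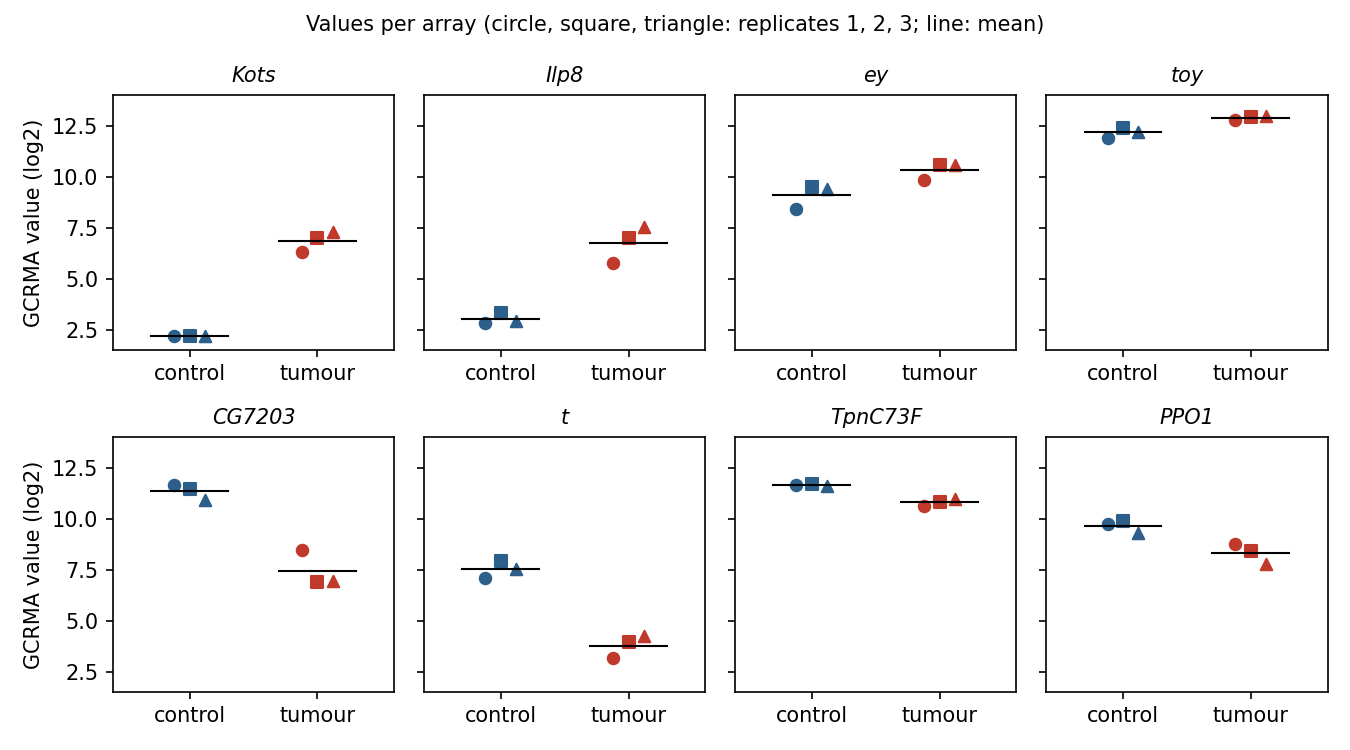
GCRMA values (log2, vertical axis) of 8 genes on each array in control (blue) and tumour (red); circles, squares and triangles are replicates 1, 2 and 3 and lines are means of 3 arrays. Kots rose from 2.18 to 6.86, t fell from 7.53 to 3.76, and the genotypes do not overlap for any of the 8 genes.

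Genes of retinal determination, the transcription factors that specify the eye field, were higher in tumour discs as a group. The paired fit called 9 of 11 tested members higher and none lower; the unpaired fit called 0, and adjusted over the list alone these counts were 11 and 6. Beside ey, so rose by 0.64 ± 0.053 (SE of the paired fit, adjusted p = 0.0073), dac by 0.69 ± 0.058 (adjusted p = 0.0075) and the ey paralogue toy by 0.72 ± 0.075 (adjusted p = 0.012). The median change was 0.69 log2 (camera adjusted p = 3.1e-07). With an estimated correlation the call was lost (adjusted p = 0.54 unpaired, 0.48 paired). With replicates 2 and 3 alone 9 members were called, 8 of them shared with the paired fit; tio was lost (adjusted p = 0.075) and eyg gained (adjusted p = 0.032). Without control replicate 1 the median was 0.44, while the median over all tested probe sets moved from 0.051 to -0.075.

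Genes of the morphogenetic furrow and photoreceptor specification followed in the same direction. Of 18 tested members 8 were called higher in the paired fit and 0 in the unpaired fit, and adjusted over the list alone 13 and 2. The Runx gene lz rose by 0.62 (adjusted p = 0.012), the neuronal marker elav by 0.52 (adjusted p = 0.014), the photoreceptor membrane protein gene chp by 0.45 (adjusted p = 0.025) and aos, an inhibitor of EGFR signalling, by 0.52 (adjusted p = 0.027), all from the paired fit. The median was 0.30 (camera adjusted p = 5.2e-06, or 0.43 with an estimated correlation). Without control replicate 1 it was 0.17, while the median over all tested probe sets was -0.075 against 0.051.

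Antennal patterning genes went the other way. The paired fit called 2 of 8 tested members lower, Dll, which specifies distal appendages (-0.61, adjusted p = 0.035), and en (-0.35, adjusted p = 0.048); adjusted over the list alone 5 were lower, and the unpaired fit called 0. The median was -0.36 (camera adjusted p = 0.00029; adjusted p = 0.43 with an estimated correlation). With replicates 2 and 3 alone no member was called by limma and the list kept its call (adjusted p = 0.0032). Of 2 tested Hox genes, Scr fell by 0.95 in the paired fit (adjusted p = 0.024) and Dfd was at -0.20 (adjusted p = 0.12).

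Targets of Notch signalling, the pathway that Delta activates, were higher for 6 of 13 tested members in the paired fit and for 0 in the unpaired fit, and adjusted over the list alone for 7 and 2. The Bearded-family gene Brd rose by 0.48 (adjusted p = 0.013), and the Enhancer of split genes E(spl)mdelta-HLH by 0.41 (adjusted p = 0.020), E(spl)m3-HLH by 0.44 (adjusted p = 0.030) and E(spl)m4-BFM by 0.25 (adjusted p = 0.031). The median was 0.19 (camera adjusted p = 0.010; adjusted p = 0.67 with an estimated correlation), against 0.31 without tumour replicate 1, 0.10 without control replicate 1 and 0.12 with arrays centred on ribosomal protein genes. The median over all tested probe sets moved in the same directions in these settings, from 0.051 to 0.15, -0.075 and -0.012. With replicates 2 and 3 alone 4 of the 6 genes were called, and E(spl)m4-BFM was not (adjusted p = 0.055). None of 13 tested components of the pathway itself was called by limma in either fit, though adjusted over the list alone 2 were higher in the paired fit; fng was at 0.25 (adjusted p = 0.055 paired) and O-fut1 at 0.23 (adjusted p = 0.056 paired), with a list median of 0.12 (camera adjusted p = 0.16).

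**Figure D3:**
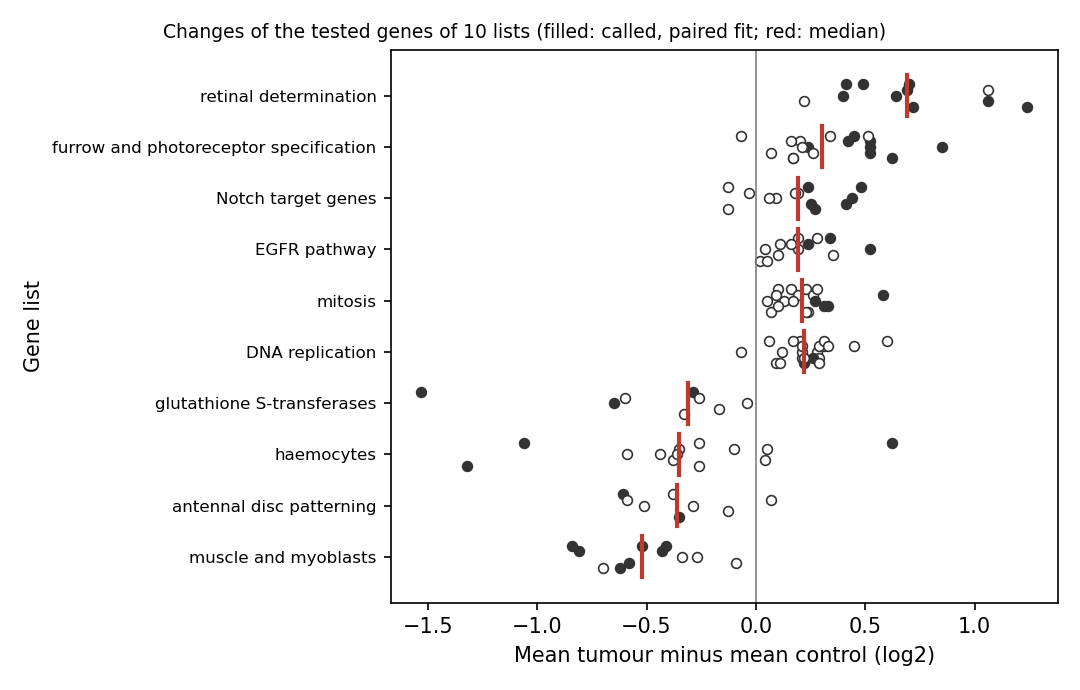
Mean log2 change, tumour minus control (horizontal axis), of each tested gene in the 10 lists past 0.05 with camera's preset correlation (vertical axis); filled points passed 0.05 in the paired fit and red lines are list medians. Medians run from 0.69 for retinal determination to -0.52 for muscle and myoblasts.

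Among other signalling lists, the EGFR pathway had 3 of 13 tested members called higher in the paired fit, Cbl by 0.34, aos by 0.52 and aop by 0.24, and 5 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.017; adjusted p = 0.67 with an estimated correlation). That median was 0.32 without tumour replicate 1, 0.11 without tumour replicate 2, 0.05 without control replicate 1, and 0.12 both with replicates 2 and 3 alone and with ribosomal centring. In these settings the median over all tested probe sets was 0.15, 0.007, -0.075, 0.037 and -0.012, against 0.051. Of 6 tested JAK/STAT members, the ligand gene upd1 rose by 1.28 in the paired fit (adjusted p = 0.011), and the list was not called (camera adjusted p = 0.18). In the Hedgehog list ihog rose by 0.27 and ci by 0.34 of 11 tested genes in the paired fit. In the Wingless list dlp (-0.28) and Wnt6 (-0.41) fell in the paired fit, of 4 tested genes, and neither was called with replicates 2 and 3 alone (adjusted p = 0.088 and 0.084). None of 10 Dpp pathway genes was called; sax was at 0.27 (adjusted p = 0.056 paired). The Hippo list had 1 of 13 called, dlp again, with a median of 0.04 while camera's direction was down. None of these last 4 lists passed with camera, whose adjusted p was 0.46, 0.30, 0.17 and 0.96.

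Cell-cycle lists shifted upward by small amounts. Of 22 tested DNA replication genes 2 were called higher in the paired fit, PCNA by 0.26 (adjusted p = 0.033) and Mcm6 by 0.22; 2 were called adjusted over the list alone. The list median was 0.22, and 21 of 22 members had a positive difference (camera adjusted p = 0.0078; adjusted p = 0.69 with an estimated correlation). Of 18 tested mitosis genes 4 were called higher in the paired fit and 9 adjusted over the list alone. They were the condensin gene barr (0.33), tum (0.27), the separase-complex gene thr (0.58) and the cyclin gene CycB3 (0.31). The mitosis median was 0.21 (camera adjusted p = 0.0025; adjusted p = 0.67 with an estimated correlation). Without tumour replicate 1, control replicate 1 or control replicate 2 the replication median was 0.37, 0.06 and 0.34 and the mitosis median 0.32, 0.08 and 0.33. The median over all tested probe sets moved in the same directions, from 0.051 to 0.15, -0.075 and 0.11. With replicates 2 and 3 alone Mcm6 was not called (adjusted p = 0.13), PCNA and Cdc6 were (adjusted p = 0.046 and 0.042), and limma called 0 mitosis genes, where the adjusted p of the 4 named lay from 0.052 to 0.10. None of 16 genes of growth and ribosome biogenesis was called by limma in either fit, and their median was -0.02 (camera adjusted p = 0.70). None of 6 tested apoptosis genes was called in either fit; adjusted over the list alone 2 were higher and 1 lower in the paired fit, with Debcl at 0.27 (adjusted p = 0.067 paired) and a list median of -0.01 while camera's direction was up (adjusted p = 0.96).

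The JNK and tissue damage list moved both ways. Beside Ilp8, which the unpaired fit also called, the matrix metalloproteinase gene Mmp2 rose by 0.45 in the paired fit (adjusted p = 0.031). The metalloproteinase inhibitor gene Timp fell by 0.74 (adjusted p = 0.0071), and so did cher (-0.42, adjusted p = 0.020) and the TNF receptor gene wgn (-0.44, adjusted p = 0.026), out of 16 tested members. The median was 0.06 and the mean 0.19, while camera's direction was down (adjusted p = 0.89). Fry's mixed test, for change in either direction, called the list in both fits (adjusted p = 3.7e-05 unpaired, 0.0057 paired). Ilp8 was the only member called in the unpaired fit, and 11 of the 16 were not called in the paired fit. The mixed test was not run without Ilp8, so how far other members carry it is open. Of 8 heat shock and stress genes Gadd45 fell by 1.27 in the paired fit (adjusted p = 0.047), and the list was not called (camera adjusted p = 0.18). Glutathione S-transferases, enzymes of detoxification, were lower for 3 of 8 tested members in the paired fit and 5 adjusted over the list alone. They were GstE5 (-1.53, adjusted p = 0.012), GstD9 (-0.65, adjusted p = 0.031) and GstD1 (-0.29, adjusted p = 0.047). The median of these 8 was -0.31 (camera adjusted p = 9.8e-05; adjusted p = 0.43 with an estimated correlation). With no filter on low values, over members near the floor as well, it was -0.02 (camera adjusted p = 0.0019).

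Markers of cells other than disc epithelium were measured beside these groups. Muscle and myoblast genes were lower for 7 of 11 tested members in the paired fit and 8 adjusted over the list alone, and for TpnC73F in the unpaired fit as well. The smallest p-values were those of the tropomyosin gene Tm2 (-0.62, adjusted p = 0.0066), the troponin C gene TpnC73F (-0.84, adjusted p = 0.010), the myosin light chain gene Mlc1 (-0.43, adjusted p = 0.021) and bt (-0.81, adjusted p = 0.024). With replicates 2 and 3 alone 5 members were called lower, 4 of them shared with the paired fit, and bt was not called (adjusted p = 0.051). The median was -0.52 (camera adjusted p = 8.2e-10; adjusted p = 0.39 with an estimated correlation). Of 13 haemocyte genes PPO1 (-1.32, adjusted p = 0.0079) and PPO2 (-1.06, adjusted p = 0.017) fell in the paired fit; with replicates 2 and 3 alone PPO1 was not called (adjusted p = 0.057). Both encode prophenoloxidases of crystal cells, while lz, which also marks eye cells and stands in the photoreceptor list, rose. The haemocyte median was -0.35 (camera adjusted p = 0.0078; adjusted p = 0.67 with an estimated correlation), with medians of -0.03, -0.67 and -0.25 in pairs 1, 2 and 3. It was -0.54 without control replicate 1 and -0.10 without control replicate 2, where the median over all tested probe sets was -0.075 and 0.11, against 0.051. Without tumour replicate 3 the haemocyte list was no longer called (camera adjusted p = 0.090). Of 6 glial genes Gs2 (-1.37, adjusted p = 0.0032) and moody (-0.41, adjusted p = 0.046) fell in the paired fit, moody not with replicates 2 and 3 alone (adjusted p = 0.051), with a list median of 0.00, a mean of -0.22 and camera's direction down (adjusted p = 0.43). Of 3 tested genes of the tracheal list, bnl, an FGF ligand made by tissues that attract tracheae and so no marker of tracheal cells themselves, fell by 0.89 in the paired fit (adjusted p = 0.043). The others, verm and serp, were at 0.19 and 0.05 (adjusted p = 0.085 and 0.48 paired), and adjusted over the list alone 1 gene was higher and 1 lower. Of 8 neuroblast and neuron genes elav, also in the photoreceptor list, was the 1 called (camera adjusted p = 0.085). No fat body, salivary gland or antimicrobial peptide gene of the lists was tested.

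Of 9 glycolysis genes Gapdh1 (-0.34) and Tpi (-0.34) fell in the paired fit. Of 13 ecdysone response genes ImpL2 (-0.48) and ImpE1 (-0.37) fell and ftz-f1 rose by 0.89 in the paired fit; with replicates 2 and 3 alone Tpi, ImpE1 and ftz-f1 were not called (adjusted p = 0.068, 0.098 and 0.18). Both lists missed the threshold in the unpaired test (camera adjusted p = 0.055 for each) and passed it in the paired test (adjusted p = 0.0066 for each), but not with an estimated correlation (adjusted p = 0.48 for each, paired). None of 18 Polycomb and trithorax genes was called by limma in either fit; ash2 was at 0.26 (adjusted p = 0.054 paired), the median was 0.15, and camera gave adjusted p = 0.081 unpaired, 0.041 paired and 0.60 paired with an estimated correlation. None of 8 genes of histone deacetylation and methylation was called, with HDAC4 at 0.59 (adjusted p = 0.088 paired; camera adjusted p = 0.18). None of 13 genes of cell polarity and adhesion was called, with shg at 0.27 (adjusted p = 0.056 paired; camera adjusted p = 0.18). None of 5 temporal and oncofetal factors was called, with Syp at 0.20 (adjusted p = 0.22 paired; camera adjusted p = 0.56). Of 3 tested germline genes krimp, of the piRNA pathway, rose by 2.01 in the paired fit from near the floor (adjusted p = 0.012).

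Over all lists, 10 of 28 lists passed 0.05 with camera's preset correlation in the unpaired fit, 6 upward and 4 downward, and 13 in the paired fit. With an estimated correlation 0 lists passed in either fit, with 2 under an unadjusted p of 0.05 in the unpaired fit and 0 in the paired fit. The directional fry test called 0 lists in both fits, with 5 and 13 under an unadjusted p of 0.05, and its mixed test, which asks for change in either direction, called 7 and 18. Of the 7, the JNK list and the neuroblast and neuron list (adjusted p = 0.014) were not called by camera.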

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

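Some tests were chosen only after the results were seen. They were a fit with replicate 1 against replicates 2 and 3 as a block, the fit without the replicate 1 arrays and the paired list test with an estimated correlation. The unpaired fit called 41 probe sets and 33 genes, 9 higher and 24 lower. A stricter filter gave 41 probe sets, no mean-variance trend 39, robust moderation 32 and a pseudocount 39. With no filter, which adds probe sets at the floor to the adjustment and the variance trend, it called 2 probe sets and 1 gene, 0 higher and 1 lower, by limma (682 genes at an unadjusted p under 0.05). With an adjusted p of 0.01, 1 gene was called on its brightest probe set, 1 higher and 0 lower. GV1 passed that threshold too, on a probe set that was not its brightest (limma adjusted p = 0.004). A 2-fold minimum left 25 genes, 7 higher and 18 lower. The mean of a gene's probe sets gave 43 genes, 13 higher and 30 lower. Centring arrays on the median of all probe sets gave 27 probe sets and 19 genes, 13 of them lower. Quantile normalization once more gave 213 and 179, 51 higher and 128 lower, and centring on ribosomal protein genes gave 193 and 160, 31 higher and 129 lower. The share of called probe sets that were higher was 39.0% as deposited, 48.1% with median centring, 31.9% after quantile normalization and 23.3% with ribosomal centring. Pairing by replicate number as a block gave 730 and 609, 262 higher and 347 lower; array weights, whose estimation did not converge fully, gave 1666 and 1356, 624 higher and 732 lower. Replicate 1 against replicates 2 and 3 as a block gave 1179 and 970, 494 higher and 476 lower. That split was taken from these same data, and no label names it as a batch. Leaving out both replicate 1 arrays gave 550 and 462, 192 higher and 270 lower. Leaving out 1 array gave 0 to 19 probe sets and 0 to 13 genes, 0 to 3 higher and 0 to 10 lower, with fewer samples in the fit. The causes of the other differences were not tested.

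Under alternatives the 19 named rises and falls had 340 values, of which 202 kept direction and call. Another 138 kept direction but not the call, 102 of them with 1 array left out, and 0 reversed. With 1 array left out none could reverse, since these genes were chosen for values that do not overlap between genotypes. The adjusted p ran from 2.3e-06 to 0.29. All 19 were called in the paired fit. The gene list tests went from 10 lists to 0 with camera's estimated correlation, 0 with directional fry and 0 with the replicate block and an estimated correlation. With the preset correlation the haemocyte list lost its call without tumour replicate 3 (adjusted p = 0.090), and the other 9 lists passed with each array left out. Beside the pairing's effects given with each result, it changed no call of a list.

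Signs reversed for small values that neither limma nor camera called in the unpaired fit, 24 of 560 for lists; of these lists Polycomb and trithorax passed in 5 of 20 alternatives and heat shock in 1 of 20, each with its first sign. With ribosomal centring psq was -0.02 and the Hedgehog and Hippo medians were -0.04 and -0.03. After quantile normalization the Hedgehog median was -0.02. With no filter the apoptosis median was 0.03 and the temporal factor median -0.02. With array weights apoptosis was 0.09, Hippo -0.05 and heat shock 0.02, and without the replicate 1 arrays apoptosis was 0.09. With 1 array left out Delta ran from -0.03 to 0.45 and psq from -0.04 to 0.13. The list medians ran from -0.08 to 0.16 for apoptosis, -0.05 to 0.14 for JNK, -0.10 to 0.21 for Hedgehog, -0.27 to 0.01 for Wingless and -0.11 to 0.11 for Hippo. They ran from -0.01 to 0.23 for Polycomb and trithorax, -0.03 to 0.20 for polarity, -0.11 to 0.10 for growth and -0.30 to 0.03 for heat shock. The glial median, 0.00 as deposited, ran from -0.27 to 0.16. With 1 array left out the median over all tested probe sets itself ran from -0.075 to 0.15, against 0.051 with all arrays. Among the 19 named rises and falls, signal near the floor limits Kots, Ilp8, t and CG11854, whose lower group had a mean under a log2 value of 4.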

Other observations

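All tests in this part other than the counts of splits were chosen after the results were seen. In place of 6 families first picked by eye, all 81 groups of at least 5 tested genes whose symbols share their leading letters were screened for genes called in the paired fit, and 8 held more than chance gives (one-sided Fisher's exact test, which treats genes as independent). Subunits of the proteasome, the protease that degrades ubiquitin-tagged proteins, made up 4 of the 8. The paired fit called 5 of 6 Prosalpha genes lower (adjusted p = 0.0017), 5 of 6 Prosbeta genes (adjusted p = 0.0017), 6 of 10 Rpn genes (adjusted p = 0.0025) and 4 of 5 Rpt genes (adjusted p = 0.0049), and none higher. The changes were small, with medians of -0.24, -0.30, -0.26 and -0.27, and all 4 medians were negative under the 3 other scalings as well. Those scalings moved the median over all tested probe sets only from 0.051 to between -0.012 and 0.06. Shifts of that size could not reverse these signs, so this is no separate support. The unpaired fit called none of these genes by limma, with an unadjusted p under 0.05 for 3, 0, 1 and 1, and with replicates 2 and 3 alone 1, 4, 3 and 1 were called, 1, 4, 2 and 1 of them shared with the paired fit. Camera's adjusted p was 0.00087, 0.0037, 0.00019 and 0.030 for these 4 groups, and adjusted p = 0.99 for each with an estimated correlation.

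The other 4 groups were Cpr cuticle proteins, which build the exoskeleton, imaginal disc growth factors (Idgf), odorant-binding proteins (Obp) and COX subunits of mitochondrial cytochrome c oxidase. Of 14 Cpr genes the paired fit called 6 lower, among them Cpr31A (-2.38) and Cpr49Ac (-1.29), and 1 higher, Cpr97Ea (1.35). The fall of Cpr31A is a lower bound, since its tumour values lay near the floor. The unpaired fit called 1, and replicates 2 and 3 alone gave 5, Cpr31A not among them (limma adjusted p = 0.053). For the Cpr group the Fisher adjusted p was 0.0025 and the camera adjusted p 5.9e-05, or 0.45 with an estimated correlation. Of 5 Idgf genes 4 were lower, including Idgf6 (-0.65) and Idgf2 (-0.63), with 0 in the unpaired fit by limma (3 at an unadjusted p under 0.05) and 3 with replicates 2 and 3 alone (Fisher adjusted p = 0.0049; camera adjusted p = 0.00087; adjusted p = 0.75 with an estimated correlation). Of 10 Obp genes 2 were higher, Obp44a and Obp83g (0.56), and 3 lower, with Obp19d (-1.20) the lowest, against 1 in the unpaired fit and 4 with replicates 2 and 3 alone (Fisher adjusted p = 0.014; camera adjusted p = 0.19; adjusted p = 0.99 with an estimated correlation). Of 7 COX genes 4 were lower, COX7C (-0.35) most, with 0 in the unpaired fit by limma (4 at an unadjusted p under 0.05) and 3 with replicates 2 and 3 alone (Fisher adjusted p = 0.022; camera adjusted p = 0.00014; adjusted p = 0.99 with an estimated correlation). Over all 81 groups camera called 12 with the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05.

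Of 10 genes with several tested probe sets and a change of at least 2-fold in the paired fit on 1 of them, 6 had another probe set called the same way and 4 had none. In mbl, counted among the 6, 1 probe set rose by 1.72 and another by 0.56 (adjusted p = 0.033 in the paired fit). Its remaining probe sets lay from -0.05 to 0.11 and were not called. In RFeSP 1 probe set rose by 5.03, a lower bound since its control values lay near the floor, and the other was at -0.36 (adjusted p = 0.098 in the paired fit). In gkt both probe sets rose, by 2.21 and 1.23.

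The real grouping gave 41 probe sets and 33 genes in the unpaired fit, and 1 of the 10 splits of the arrays into 3 against 3 gave as many, itself, with at most 1 probe set and 0 genes in any other. Of the 4 splits that part all 3 pairs, 1, the real one, gave as many as 609 genes in the paired fit, and the others gave 0. For gene lists 2 of 10 splits gave as many as the real 10, and the highest other gave 12, with tumour replicates 1 and 2 and control replicate 2 on one side. In the paired fit the real split called 13 lists and the 3 others that part all pairs called 11, 6 and 2. These splits are too few for a share under 0.05.

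The replicate 1 arrays of both genotypes lay apart from the rest. A shift of whole arrays did not account for this, since the deviations of the 2 replicate 1 arrays still correlated at 0.778 across probe sets after quantile normalization. RNA with a stronger 3' bias may contribute. The mean 3'-minus-5' difference of 4 control genes was 0.253 higher on replicate 1 arrays than on the others of their genotype, at 1.12 against 0.744 and 0.779 in tumour and 1.01 against 0.938 and 0.788 in control. No biological explanation was tested.

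The retinal determination list had a positive median and the antennal, muscle and haemocyte lists negative ones, each called with camera's preset correlation and none with an estimated one (adjusted p = 0.54, 0.43, 0.39 and 0.67). Fewer muscle cells and haemocytes on the discs would raise eye and antennal genes alike. Instead the retinal median exceeded the antennal median by 1.05, and by 1.13, 0.95 and 0.91 in the 3 pairs. That explanation alone would not give this difference. The contrast restates the signs by which the pattern was picked, so it is no separate test of the explanation. A larger eye share of the tumour disc stays open as a hypothesis. The retinal median exceeded the photoreceptor median by 0.39 (permutation p = 0.001 across genes, which are not independent), where an equal rise might be predicted, yet many members of both lists are also expressed outside the eye, which could make them differ. An effect of the driven genes on eye identity was not tested.

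The ecdysone synthesis genes spok and sad fell in the paired fit (-2.29, adjusted p = 0.047, and -1.28, adjusted p = 0.012), but not in the unpaired fit (adjusted p = 0.50 and 0.42) or with replicates 2 and 3 alone (adjusted p = 0.21 each). These genes are known from the ring gland, and less of it beside the dissected discs is a candidate explanation. The 3 other tested genes of an 11-gene list had a median of -0.14, and 4 others, nvd and dib among them, lay under the filter with no value over 2.62, too few measured genes to decide. A change within the discs stays open and was not tested.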
